A study of Mus musculus with 2 samples.

How the data were processed

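A count table and a transcript annotation were used for each library of gastrocnemius RNA. The authors deposited whole read counts per transcript model, 1 table per library, and a matching annotation of every model. Per the file headers each row gives the gene, the model, its number of exons, its length and a class, and per the deposited descriptions of the files the counts were made per library from a filtered alignment on mm10 with the GENCODE M21 annotation. The attribute names point to TALON. The aligner, the read correction and the versions are not given in the sources used here. Every annotated model had an identifier, exons and introns equal to those of the GENCODE M21 reference (16090 of 16090 in replicate 1 and 12749 of 12749 in replicate 2), whose primary assembly lists 55536 genes.

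Counts were used as deposited. ERCC spike-in RNAs, recognised by their own contigs, were set aside (other spike-in RNAs named in the labels were not analysed here), and CPM were counts per 1000000 remaining reads of the library (1094607 and 626289). CPM with annotated models alone were counts per 1000000 reads on annotated models (770685 and 434422), so they are on another scale. Counts per gene summed all models of an annotated gene, and genes were keyed by identifier because 14 rows shared a symbol with another. Models not in the annotation carry identifiers of their library, so they were joined by gene, strand and the complete chain of introns. Antisense and intergenic loci were kept out of gene tables. Gene spans are those of the annotated transcripts. The transcript length of a gene was the mean length of its complete models weighted by reads, a definition set after the data were seen because Atp2a1 has almost no reads on annotated models. Complete models are those of the annotated class and of the 2 unannotated spliced classes, without partial matches and without reads that overlap a gene but not its splicing.

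With 1 group, levels are given as mean ± SD (n = 2) and no test between groups was made. Shares carry exact Clopper-Pearson 95% intervals, which, like the limit of 3 reads set by a count of 0, cover counting error only since reads carry no molecular identifiers. Libraries were compared by Fisher's exact test of each gene's reads against the library total, two-sided, with Benjamini-Hochberg adjustment over genes with at least 10 reads and a threshold of 0.05. Model shares were compared by Fisher's exact or chi-square test in genes with at least 50 reads of complete models per library. Gene lists were placed among 10000 random lists matched on mean expression in 20 bins. The common dispersion and TMM factors (1.07 and 0.938) came from edgeR 4.0.16 under R 4.3.3, and the rest was done with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

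The 25 gene lists, 23 families of related genes and 50 splicing genes, and the planned tests and alternatives, were fixed before the data were examined. Tests and alternatives added after the data were seen are named as such where they are given. Named are the 10 most abundant genes, family members with at least 5% of their family and the lowest member, up to 4 of the most abundant members of each list, the 10 genes with the largest ratio each way among those that differ and reach 50 CPM, the 15 most evenly divided and 5 most read splicing genes, and 10 genes led by a model that is not annotated. A few genes and 1 place that these rules name are not reported here.

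The tests were checked on simulated counts for the same genes. Apart from the dispersion check, counts were drawn with sampling noise alone, without the further spread that these libraries show. Recovery and wrong calls below therefore hold for that noise only and do not give rates for these data. Of 50 genes changed per size in the gene test over 7913 genes, 26% were recovered at 1.5-fold, 54% at 2-fold, 84% at 3-fold and 92% at 4-fold, with 11 calls among unchanged genes. The isoform test over 935 genes recovered 92 of 100 changed genes and called 1 unchanged gene. All 20 shifted lists and 1 of the unshifted lists left the central range of random lists. Counts that followed only the measured length trend gave 542 calls without and 1 call with the length adjustment over 7948 genes. A simulated dispersion of 0.1 was estimated as 0.103 over 7955 genes. Alternatives covered read minimums, thinning, pseudocounts, TMM, the classes of models used, and leaving out each replicate.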

Results

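Long-read RNA sequencing was used to count transcripts in the gastrocnemius, the large muscle of the calf, of male mice at postnatal day 14. The animals were B6CASTF1/J, the first-generation offspring of a cross between C57BL/6 and CAST mice. The series holds 1 group with 2 biological replicates, each made from 2 µg of RNA, so it describes a level and its spread in 1 tissue at 1 age and holds no contrast between conditions. The labels number the libraries as biological replicates and give 1 donor identifier for both, and their biosample names speak of several males. Whether each replicate was a pool of animals, and whether the replicates came from separate animals, is not stated, so each SD below is the spread between these libraries, possibly between pools, and may in part be technical. Replicate 1 held 1141661 reads and replicate 2 held 642362. After spike-in RNAs were set aside, 1094607 and 626289 reads remained, of which 98.0% and 96.7% fell in annotated genes. At least 1 read was found for 13715 annotated genes in replicate 1 and 12149 in replicate 2, and 11160 genes were seen in both. The files listed 76001 and 49981 transcript models, of which 61.0% and 60.3% rested on a single read. A count of 3 reads, the upper limit that a count of 0 allows, corresponds to 2.74 CPM (reads of a gene per 1000000 reads of the library) in replicate 1 and 4.79 CPM in replicate 2. Coordinates are on mm10.

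The 3 most abundant genes were Atp2a1, the calcium pump of the fast-fibre sarcoplasmic reticulum, at 76580 ± 24230 CPM (SD, n = 2), Acta1, the skeletal muscle actin, at 75960 ± 4887 CPM, and Ckm, the muscle creatine kinase, at 68090 ± 2142 CPM. Together they took 24.0% of the reads of replicate 1 and 20.2% of those of replicate 2. Next came fast troponin C (Tnnc2, 30160 ± 11220 CPM), the fast regulatory myosin light chain (Mylpf, 26760 ± 6879 CPM), alpha-tropomyosin (Tpm1, 26030 ± 2520 CPM) and the fast essential light chain (Myl1, 16860 ± 4402 CPM). Myh4, the myosin heavy chain of the fastest (type 2B) fibres, stood at 14170 ± 3827 CPM, the mitochondrial ADP/ATP carrier Slc25a4 at 13140 ± 2047 CPM, and aldolase A (Aldoa) at 9960 ± 1623 CPM. These 10 genes held 36.5% and 35.0% of the reads.

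Within the families of muscle proteins, the adult fast member led nearly everywhere. Of the myosin heavy chain reads, Myh4 (chromosome 11, 67238029 to 67260446) took 79.5% ± 3.23 (SD, n = 2) and Myh1, the type 2X gene, 14.3% ± 2.54. Myh2 held 3.19% ± 0.380 and the slow Myh7 2.68% ± 0.292, while the neonatal Myh8 held 0.220% ± 0.0206 and the embryonic Myh3 0.0895% ± 0.00236. Myh4 reads outnumbered those of Myh8 by 364-fold ± 48.8 and those of Myh3 by 889-fold ± 12.6, differences larger than the spread between the replicates. The annotated spans of these chromosome 11 genes do not overlap, but 98 of 18473 Myh4 reads in replicate 1 and 22 of 7180 in replicate 2 were on models that reached into another gene of the family, as were 21 of 3851 and 7 of 1098 Myh1 reads, 1 of 56 and 0 of 18 Myh8 reads, and 0 of 21 and 0 of 8 Myh3 reads. Whether other reads were assigned to the wrong one of these similar genes was not tested, and this limit applies to the shares and both folds. Exact Clopper-Pearson 95% intervals for the Myh1 share, 15.6% to 16.6% in replicate 1, cover counting error only. When annotated models alone were counted, the shares were 57.3% for Myh4, 30.97% for Myh1, 7.27% for Myh7 and 0.113% for Myh8, with 13 and 1 reads left for Myh8 and 14 and 1 for Myh3.

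**Figure D1:**
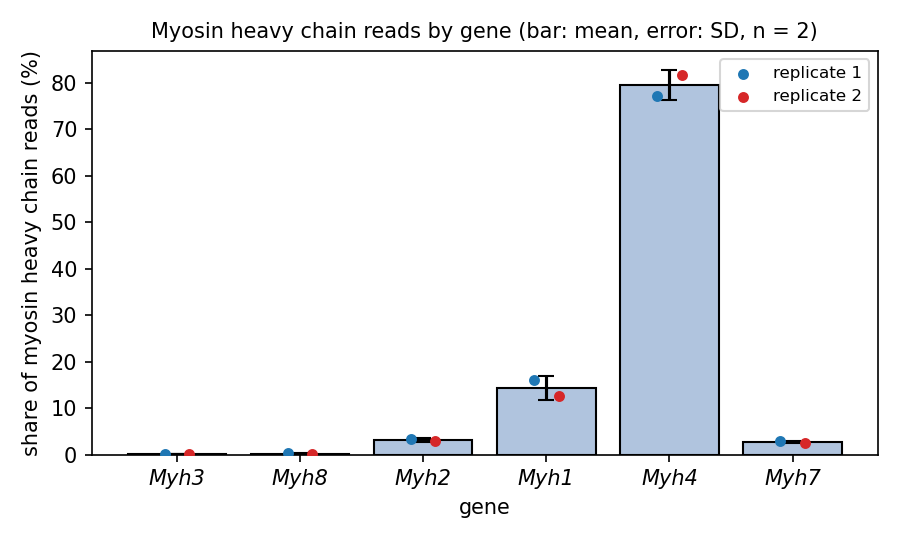
Share of all myosin heavy chain reads (y axis, percent) taken by each of 6 genes (x axis). Bars are means and error bars SD over n = 2 libraries, and points are the individual libraries. Myh4 lies at 77.2% in replicate 1 and 81.8% in replicate 2, and the developmental genes Myh3 and Myh8 lie close to 0.

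The same held for the thin filament and its regulators. Acta1 took 96.8% ± 0.202 of sarcomeric actin reads and the cardiac and fetal Actc1 3.20% ± 0.202. Tnni2 held 96.5% ± 0.127 of troponin I reads, with 1 read of the cardiac Tnni3 in replicate 2 and none in replicate 1, and Tnnc2 held 98.8% ± 0.247 of troponin C reads against 1.22% ± 0.247 for the slow Tnnc1. With all models counted, troponin T was the most mixed of the thin filament families, with Tnnt3 at 70.6% ± 8.83, the slow Tnnt1 at 29.2% ± 8.81 and the cardiac Tnnt2 at 0.169% ± 0.0254. With annotated models alone the Tnnt3 share was 100%, from 4 and 3 reads, as was that of Tnni2, from 41 and 47 reads, and Tnnt1 had 0 reads in both libraries. Tpm1 took 86.5% ± 0.0207 of tropomyosin reads, Tpm2 12.1% ± 0.136 and Tpm3 1.43% ± 0.115. Among light chains, Myl1 took 98.5% ± 0.135 of the essential set, with Myl6b lowest at 0.0131% ± 0.0185 (4 and 0 reads), and Mylpf took 99.6% ± 0.0214 of the regulatory set, in which the atrial Myl7 had 0 reads in both libraries.

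With all models counted, structural families followed the fast pattern with more overlap than the actin, troponin I and troponin C families, and calcium-handling families with little. Actn3, the alpha-actinin of fast fibres, held 73.4% ± 1.49 of alpha-actinin reads and Actn2 26.6% ± 1.49. Mybpc2 took 87.2% ± 1.53 of myosin-binding protein C reads and Mybpc1 12.8% ± 1.53, or 3.25% with annotated models alone, and no read of the cardiac Mybpc3 was found. Myom2 held 62.6% ± 1.18 of myomesin reads, Myom1 36.6% ± 1.88 and Myom3 0.840% ± 0.696 (5 and 10 reads). Atp2a1 took 99.8% ± 0.0285 of calcium pump reads, with Atp2a3 lowest at 0.00280% ± 0.000168 (3 reads and 1 read), but the Atp2a1 share was 7.76%, from 5 and 4 reads, when only annotated models were counted. Casq1 held 98.8% ± 0.209 of calsequestrin reads and Casq2 1.25% ± 0.209. Of the acetylcholine receptor subunits that are exchanged during maturation of the neuromuscular junction, the adult Chrne had 35 and 19 reads and the fetal Chrng 5 and 0, a Chrne share of 93.8% ± 8.84.

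Enzymes and mitochondrial subunits likewise came from the muscle-type genes. Ckm held 98.3% ± 0.312 of creatine kinase reads, the mitochondrial Ckmt2 1.63% ± 0.297, and Ckmt1 had 0 reads. Eno3 held 94.4% ± 1.01 of enolase reads and Eno1 5.62% ± 1.01, or 0.344% with annotated models alone, and Eno2 had 0 reads. Pgam2 took 99.3% ± 0.342 of phosphoglycerate mutase reads and Pgam1 0.718% ± 0.342, Ldha 98.4% ± 0.127 of lactate dehydrogenase reads and Ldhb 1.61% ± 0.127, and Pygm 99.7% ± 0.227 of glycogen phosphorylase reads with Pygl lowest at 0.1004% ± 0.142. In cytochrome oxidase, the muscle subunit Cox6a2 held 96.2% ± 0.548 against 3.80% ± 0.548 for Cox6a1 and Cox8b 82.0% ± 3.03 against 18.02% ± 3.03 for Cox8a. Subunit 7a was the exception, with the muscle form Cox7a1 at 39.6% ± 6.93 and the ubiquitous Cox7a2 at 60.4% ± 6.93. Slc25a4 took 94.6% ± 2.36 of ADP/ATP carrier reads and Slc25a5 5.37% ± 2.36. The Slc25a5 share was 2.21% with annotated models alone and 1.70% without reads that overlap the gene but not its splicing.

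Summed over the lists, the 15 fast fibre genes held 20.2% ± 0.934 of all reads, led by Atp2a1, Tnnc2, Mylpf and Myl1. The 11 slow fibre genes held 0.309% ± 0.0538, led by Tnnt1 (816 ± 562 CPM), Myh7 (488 ± 201 CPM), Tpm3 (430 ± 7.17 CPM) and Tnnc1 (358 ± 62.3 CPM). The 14 developmental genes held 0.572% ± 0.103. Most of that came from Actc1 (2520 ± 325 CPM), the imprinted noncoding RNA H19 (1833 ± 435 CPM) and the cell cycle inhibitor Cdkn1c (823 ± 245 CPM), whereas Myh8 stood at 39.95 ± 15.9 CPM and Myh3 at 16.0 ± 4.53 CPM. Myog, a myogenic transcription factor, was at 145 ± 4.17 CPM. The 14 imprinted genes summed to 3169 ± 758 CPM, H19 and Cdkn1c being the highest, followed by the growth factor Igf2 at 104 ± 6.87 CPM.

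Glycolysis and glycogen genes summed to 44620 ± 3628 CPM, with Aldoa, Eno3 (9492 ± 410 CPM), Ldha (7464 ± 337 CPM) and Pgam2 (4581 ± 1545 CPM) highest. Gapdh, another enzyme of that pathway, was listed at 51.5 ± 10.8 CPM, a count that is uncertain because many near-identical processed copies of it lie in the genome. The 20 nuclear genes of oxidative phosphorylation summed to 32540 ± 6215 CPM, led by Atp5b (5812 ± 626 CPM), Cox4i1 (4354 ± 1794 CPM), Atp5a1 (2927 ± 885 CPM) and Ndufa4 (2718 ± 1842 CPM). Mitochondrially encoded genes summed to 1692 ± 335 CPM, with mt-Cytb (613 ± 469 CPM) and mt-Co1 (501 ± 106 CPM) highest and no read for mt-Nd4l, mt-Nd6 or mt-Atp8. Reads on the mitochondrial chromosome made up 0.152% of replicate 1 and 0.198% of replicate 2. Whether filtering of the alignment removed others, or reads of mt-Nd4l, mt-Nd6 or mt-Atp8 were counted for neighbouring genes, was not tested. A count of 0 thus does not show that these genes were silent. Excitation-contraction coupling genes summed to 93070 ± 24750 CPM, or 14260 CPM with annotated models alone, and after Atp2a1 the highest were Casq1 (8675 ± 1558 CPM), the sarcoplasmic reticulum protein Srl (2659 ± 896 CPM) and the calcium-binding Hrc (1777 ± 1540 CPM). The ryanodine receptor Ryr1 (323 ± 116 CPM), Ttn (174 ± 72.0 CPM) and Plec (134 ± 33.2 CPM) were among the highest giant transcripts, which summed to 941 ± 330 CPM, or 6.20 CPM with annotated models alone. The models found for Ttn and Ryr1 had mean lengths of 5671 and 4864 bases, and whether they covered the full RNAs was not tested. Ribosomal protein genes summed to 4881 ± 1280 CPM, led by Rpl13 (569 ± 134 CPM) and Rpl5 (480 ± 378 CPM).

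Regulatory lists were low. Splicing regulators summed to 750 ± 73.8 CPM, or 395 CPM with annotated models alone, led by Rbm24 (181 ± 47.9 CPM) and Fxr1 (165 ± 60.9 CPM). The atrophy and growth list summed to 392 ± 154 CPM, with the ubiquitin ligase Trim63 at 187 ± 111 CPM and Igf2 next. Neuromuscular junction genes summed to 256 ± 102 CPM, led by acetylcholinesterase (Ache, 60.2 ± 28.6 CPM) and the receptor subunit Chrnb1 (39.3 ± 19.4 CPM). Immediate early and heat shock genes summed to 222 ± 38.6 CPM, led by Dusp1 (95.5 ± 38.0 CPM) and Ier2 (43.2 ± 4.72 CPM). Satellite cell and myoblast genes summed to 226 ± 11.8 CPM, mostly Myog with Mymk next at 23.8 ± 0.140 CPM. Pax7, the satellite cell factor, had 0 reads in replicate 1 and 1 in replicate 2. Cell cycle genes summed to 55.2 ± 14.9 CPM, led by Rrm2 (12.4 ± 1.79 CPM) and Pcna (11.6 ± 2.92 CPM).

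Markers of other cell types were led by connective tissue. The 12 extracellular matrix and fibroblast genes summed to 6608 ± 3684 CPM, with the collagens Col1a1 (2344 ± 2014 CPM) and Col3a1 (2179 ± 845 CPM) and Sparc (980 ± 305 CPM) highest. Erythroid genes summed to 1097 ± 461 CPM, led by the globins Hba-a1 (568 ± 257 CPM) and Hbb-bs (300.3 ± 117 CPM), whose split from their near-identical copies Hba-a2 and Hbb-bt is uncertain. Smooth muscle and pericyte genes summed to 447 ± 76.3 CPM (Acta2, 225 ± 47.3 CPM, and Rgs5, 148 ± 28.5 CPM), Schwann and nerve genes to 430 ± 173 CPM, or 263 CPM with annotated models alone (Pmp22, 204 ± 52.9 CPM, and Mbp, 74.0 ± 28.5 CPM), endothelial genes to 321 ± 83.6 CPM (Cldn5, 146 ± 61.5 CPM, and Egfl7, 74.6 ± 7.36 CPM) and tendon genes to 314 ± 191 CPM (Fmod, 128 ± 93.6 CPM, and Thbs4, 64.6 ± 41.7 CPM). Adipocyte genes summed to 187 ± 99.7 CPM, mostly Fabp4 (161 ± 66.0 CPM) with Cfd next (14.5 ± 17.9 CPM), or 69.1 CPM with annotated models alone. Macrophage and immune genes summed to 90.04 ± 3.15 CPM (Lyz2, 25.1 ± 8.42 CPM, and C1qa, 15.4 ± 1.47 CPM), and skin, cartilage and bone genes to 22.3 ± 11.2 CPM, or 11.4 CPM with annotated models alone (Col2a1, 13.5 ± 14.5 CPM, and Krt10, 7.99 ± 2.25 CPM).

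Whole-transcript counts resolved isoforms in 27 of the 50 genes of the muscle splicing list. Trdn, which anchors the calcium release complex, was the most divided, its leading model, the single-exon Trdn-204, taking 3.15% of reads in replicate 1 and 24.1% in replicate 2. These shares rest on 5 of 159 and 28 of 116 reads of complete models. Most Trdn reads, 864 and 1055 in all, were on other classes of models and did not enter them. Tnnt3 was spread over 139 models. Its leading model, at 18.3% ± 1.34, carried the 41-base stretch at chromosome 7, 142514326 to 142514366, and the next, at 13.3% ± 1.18, the 41-base stretch at 142513665 to 142513705, a pair of alternative exons near the 3′ end. Both models also differed further 5′. There, 111 bases at 142510553 to 142510663 were only in the leading model and 66 bases at 142501659 to 142501724 only in the next. Nrap held 30.8% ± 6.79 and 20.4% ± 3.34 on 2 leading models that differed by 3 bases, and Fxr1 46.3% ± 2.94 and 32.6% ± 2.81 on its 2. Bin1, a membrane-shaping protein of the T-tubules, was divided between a 15-exon model at 51.2% ± 3.61 and a 14-exon model at 41.9% ± 2.51 that lacked 72 bases at chromosome 18, 32431671 to 32431742. Myl1 was divided between Myl1-202, which starts within the gene, at 61.3% ± 3.99, and Myl1-201, which starts at an upstream 352-base exon (chromosome 1, 66944792 to 66945143), at 31.1% ± 5.11. Ndrg2 had 2 nearly equal models, at 47.5% ± 2.84 and 45.4% ± 1.44, that differed in their first exon, as did those of Fhl1 at 60.2% ± 7.70 and 30.6% ± 7.96. The lamin gene Lmna held 58.5% ± 1.05 on the 10-exon Lmna-203 and 36.0% ± 0.625 on the 12-exon Lmna-201.

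Other genes of the list had a clearer leading form. Mbnl2, itself a splicing factor, had 67.0% ± 4.20 on a model lacking a 95-base exon (chromosome 14, 120404638 to 120404732) and 18.2% ± 2.59 on Mbnl2-204, which has it. Asph had 71.9% ± 2.08 on Asph-206 and 12.9% ± 0.979 on a model with 180 more bases. Ank1-208 held 81.4% ± 1.61, an annotated 10-exon model of Tpm3 84.6% ± 1.79, and unannotated models of Pdlim5 and Pdlim7 86.3% ± 6.95 and 86.9% ± 3.11. Among the genes with the most reads, an annotated 10-exon model of Tpm1 held 98.8% ± 0.0472, Ldha-202 99.2% ± 0.175 and Pkm-202 95.3% ± 0.275. Atp2a1 held 93.8% ± 0.0496 on a 22-exon model. A model that skipped its exon 21, 42 bases at chromosome 7, 126446545 to 126446586, held 3.97% ± 0.484, and this one was named after its values were seen. The form without that exon is known as the neonatal form of the pump.

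Over all 1044 genes with at least 50 reads of complete models in each library, the median share of the leading model was 95.5%, and 98.1% of the genes had the same leading model in both. The model shares of 20 of 961 genes differed between the libraries (Fisher's exact or chi-square test, Benjamini-Hochberg adjusted p under 0.05), among them 4 of the 27 list genes, and 4 when adjusted over the list alone. These were Myl1, Atp2a1, Trdn and Fhl1. The test was not adjusted for the length of models, although read share fell with length in replicate 2. For Myl1 the 803-base Myl1-202 held 58.4% in replicate 1 and 64.1% in replicate 2, and the 1082-base Myl1-201 34.7% and 27.4%. Whether length accounts for such differences was not tested. For Aldoa and Tnni2, which gave the smallest p, the files put the same chain of introns in different classes, and with the chains joined the part of reads on other models fell from 73.8% to 1.77% for Aldoa and from 92.8% to 1.94% for Tnni2, with adjusted p of 0.993 and 0.414. With chains joined, 18 of 962 genes differed.

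In 28 of 522 genes with at least 100 such reads in each library, neither library's leading model was in the annotation, and in 27 of them both libraries had the same one. The exception was Tnni2, whose leading chain of replicate 2 had another class in the file of replicate 1. The 10 with the lowest annotated share included muscle genes and housekeeping genes. The leading model of Atp2a1 had an exon 1 whose 3′ end ran 26 bases further (chromosome 7, 126462779 to 126462804) than the closest annotated transcript and lacked an 18-base exon (126462500 to 126462517), and annotated models took 0.00820% ± 0.00434 of its reads. Tnnt3 (0.415% ± 0.00558 on annotated models) and Bin1 (2.40% ± 0.861) were again among them, the leading Bin1 model carrying a 45-base stretch at chromosome 18, 32423242 to 32423286. Hacd1, a fatty acid elongation enzyme of muscle, had 91.0% ± 3.22 on 1 unannotated model. So did the isocitrate dehydrogenase subunits Idh3g (95.0% ± 2.22) and Idh3b (95.7% ± 1.45) and the mitochondrial ribosomal protein Mrpl33 (96.4% ± 2.09). Like that of Atp2a1, the leading models of Hacd1, Mrpl33 and Hnrnpk lacked a short annotated stretch, of 19, 19 and 16 bases. They instead ran 27, 8 and 16 bases further at the edge of the unannotated intron that spans it. Whether reads were aligned correctly at such short exons was not tested. The antizyme genes Oaz1 (96.6% ± 0.2996) and Oaz2 (94.3% ± 0.938) had leading models that differed from the closest annotated transcript by only 4 bases and 1 base. All junctions of both models were annotated, so they held no new splice site and are hardly distinct from the annotated form. Hnrnpk led with 46.9% ± 9.81.

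By class, annotated models took 69.9% ± 0.742 of reads (SD, n = 2), models that matched only part of an annotated intron chain 10.6% ± 0.827, models with an unannotated splice site 9.63% ± 2.72, and new combinations of annotated splice sites 3.87% ± 0.111. Reads that overlapped a gene without matching its splicing took 3.45% ± 1.57, antisense models 2.17% ± 0.805 and intergenic models 0.405% ± 0.144. Of the 13113 unannotated intron chains of replicate 2, 36.7% were also present in replicate 1, and of the 24907 of replicate 1, 19.3% were present in replicate 2. The shared chains nevertheless carried 85.4% of such reads in replicate 1 and 79.9% in replicate 2. The leading Atp2a1 model alone held 54.5% and 45.8% of them, and without it, a setting added after the data were seen, the shared chains carried 68.0% and 62.8%. It also held 72.3% and 69.1% of the reads on models with an unannotated splice site. Among chains with at least 5 reads, 97.6% of those in replicate 2 were found in replicate 1. Neither splice site motifs of unannotated junctions nor the alignment at short exons was tested, as no genome sequence was used here.

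The libraries differed from each other in transcript length and in several gene lists, connective tissue genes among them. Across 14704 genes, which are not independent replicates, log2(CPM + 1) had a Pearson correlation of 0.901 and a Spearman correlation of 0.877. A chi-square test over genes gave 9.14 times its degrees of freedom, so the libraries differed by more than sampling noise if each read is taken as an independent molecule, which reads without molecular identifiers cannot show. The same holds for Fisher's exact test, and edgeR's common dispersion corresponded to a coefficient of variation of 29.2%. Of 7955 genes with at least 10 reads, 1070 differed by Fisher's exact test at an adjusted p under 0.05, a test that compares these libraries, not conditions. Of these, 522 were higher in replicate 2, with a median transcript length of 851 bases, and 548 were higher in replicate 1, with a median of 2679 bases. TMM scaling gave 663 higher in replicate 2 and 266 higher in replicate 1, as it moved the median log2 ratio over all tested genes from -0.24 to -0.05, and adjustment for transcript length, added after the data were seen, gave 336 higher in replicate 2 and 180 higher in replicate 1. Of these 516 genes, 387 were among the 1070.

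Among abundant genes with the largest ratios, Col1a1 (log2 ratio of replicate 2 over replicate 1, -2.03), Pdk4 (-1.86), Flii (-1.79), Angptl7 (-1.73), Fmod (-1.63), Lrrc30 (-1.61), Rsrp1 (-1.49), Vcp-rs (-3.09) and AY036118 (-2.59) were higher in replicate 1. Higher in replicate 2 were Mpc1-ps (3.61), A530058N18Rik (3.54), Tsc1 (2.80), Esrra (2.67), AC154200.1 (2.65), Csrp3 (2.60), Neat1 (2.503), Lcn8 (2.14) and Gm10774 (2.11). Mpc1-ps, Gm10774 and Vcp-rs are processed pseudogenes, whose reads can be shared with their parent genes. In replicate 1 a further 186 reads were on an unannotated model at chromosome 12, 110858070 to 110858565, on the strand of Mpc1-ps and touching its span. Whether the Mpc1-ps ratio (17 and 122 reads) reflects how reads were assigned between them was not tested. Genes shorter than 500 bases had a median log2 ratio of 1.14, those of 500 to 1000 bases 0.57 and those of 4000 to 6000 bases -0.45.

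**Figure D2:**
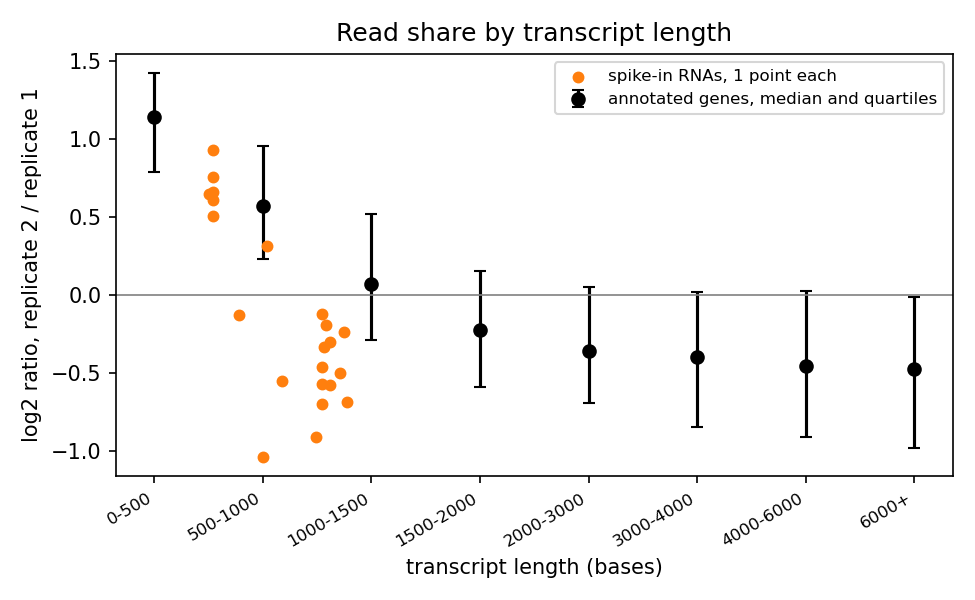
Log2 ratio of replicate 2 over replicate 1 (y axis) by transcript length in bases (x axis, bins of unequal width). Black points are medians of annotated genes with quartiles, and orange points are 22 spike-in RNAs with at least 50 reads, scaled to all spike-in reads and placed within the bins by length. The gene median goes from 1.14 under 500 bases to -0.45 at 4000 to 6000 bases.

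Several gene lists stood apart between the libraries. Of the 12 extracellular matrix and fibroblast genes, 7 were higher in replicate 1, 0 were higher in replicate 2 and 5 did not pass the Fisher's exact test, with 8 passing when adjusted over the list alone. Their median log2 ratio of replicate 2 over replicate 1 was -1.09, lower than all 10000 random lists of matched expression. Of 6 tested tendon genes, 5 were higher in replicate 1 (5 adjusted over the list alone), with a median of -1.51, again below all random lists. Neuromuscular junction genes had a median of -1.01 (percentile 0.2), atrophy and growth genes of -0.96 (percentile 1.27), splicing regulators of -0.60 (percentile 1.34) and giant transcripts of -0.69 (percentile 1.18). The last 2 lists lay inside the range of random lists once transcript length was matched too, at percentiles 8.39 and 10. The length matched was that of the models found, such as 5671 bases for Ttn and 3499 for Neb. For giant transcripts the match therefore need not hold for the full RNAs.

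The Fisher's exact test of list members, which compares these libraries, not conditions, called genes in both directions in most lists of muscle genes. Of 15 fast fibre genes, 9 (such as Myh4 and Myh1) were higher in replicate 1 and 6 (such as Tnnc2 and Mylpf) in replicate 2, with 15 passing when adjusted over the list alone. Of 11 slow fibre genes, 3 were higher each way (6 adjusted over the list alone), Tnnt1 and Csrp3 in replicate 2 and Myh7 in replicate 1 among them. Of 20 nuclear oxidative phosphorylation genes, 12 were higher in replicate 2 and 6 in replicate 1 (18 adjusted over the list alone), with the short Cox7a1, Ndufa4 and Cox8b among the former. Of 14 glycolysis and glycogen genes, 11 were higher in replicate 1 and 1, Pgam2, in replicate 2 (12 adjusted over the list alone), and of 19 ribosomal protein genes 10 were higher in replicate 2 and 0 in replicate 1 (13 adjusted over the list alone, with Rpl3, at a log2 ratio of -0.50, the 1 higher in replicate 1). Excitation-contraction coupling genes were split, with 3 higher in replicate 2 (Trdn and Hrc among them) and 5 in replicate 1 (9 adjusted over the list alone).

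Of 11 tested developmental genes, 4 (Actc1, H19, Dlk1 and Cdkn1c) were higher in replicate 1 and 1, Myl4, in replicate 2 (7 adjusted over the list alone), and of 12 imprinted genes 4 were higher in replicate 1 (5 adjusted over the list alone, with Peg3, at a log2 ratio of 1.75, the 1 higher in replicate 2). In each of the following lists the first count gives members higher in replicate 1 and the second, in parentheses, the number adjusted over the list alone that passed in either direction. These were 4 (5) giant transcripts, 1 (4) neuromuscular junction gene, which was Ache, 2 (2) atrophy and growth genes, which were Trim63 and Fbxo32, 1 (2) endothelial gene, Cldn5, and 1 (1) smooth muscle and pericyte gene, Acta2. Splicing regulators had 2 higher in replicate 1 (Mbnl2 and Rbm24) and 1 in replicate 2 (Fxr1), immediate early and heat shock genes 2 (Dusp1 and Jun) and 1 (Atf3), and mitochondrially encoded genes 3 and 1 (mt-Cytb), each list having 4 that passed when adjusted over the list alone. Both tested adipocyte genes, Fabp4 and Cfd, were higher in replicate 2 (2 adjusted over the list alone), and of the 2 tested skin, cartilage and bone genes Col2a1 was higher in replicate 1 (1 adjusted over the list alone). No satellite cell, macrophage or cell cycle gene passed, with 0 when adjusted over the list alone.

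Spike-in RNAs took 4.12% of the reads of replicate 1 and 2.502% of those of replicate 2, and 55 and 46 of them were detected. Their log2 reads had a Pearson correlation of 0.969 between the libraries across 60 RNAs. Among 22 spike-in RNAs with at least 50 reads, 505 to 1136 bases long, the 9 shorter than 800 bases had a median log2 ratio of 0.61 and the 13 longer ones -0.50.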

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

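The comparison of tissue lists after length adjustment, the joining of intron chains, the count that adds models lacking both ends and the interval of the slope difference are tests chosen after the result was seen, and the spike-in, truncation and length-matched tests were written before theirs were seen.

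Signal appeared at places outside the annotated genes, in both libraries and with at least 100 reads in each, above the limit that a count of 0 allows, and 7 of them are reported here. The strongest was antisense to Klhl31, at chromosome 9, 77656523 to 77660127, at 2770 ± 1829 CPM (SD, n = 2), followed by one antisense to Gm26917 at chromosome 17, 39843013 to 39846245, at 1298 ± 750.2 CPM. AY036118 lies close to the latter, at 39847113 to 39848035, and both were lower in replicate 2. The place had 1829 CPM in replicate 1 and 768 in replicate 2, and AY036118 had 168 and 27.1. These signals may thus not be independent, and what RNA they come from was not tested. Loci antisense to Actb (235 ± 175 CPM), Cdv3 (229 ± 160 CPM), Msrb3 (223 ± 164 CPM) and 2900097C17Rik (187 ± 64.7 CPM), and one that the annotation files call intergenic, opposite to Dyrk1b (179 ± 8.88 CPM), were the other reported places. Each was a model of 1 exon in both libraries, and priming within A-rich stretches was not tested, as no genome sequence was used here. Reads on the strand opposite to the spike-in RNAs numbered 392 in replicate 1 and 105 in replicate 2.

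Read share fell with transcript length in replicate 2 relative to replicate 1, with a Spearman correlation of -0.363 across 7955 genes. For recovery that fell with length after the spike-in RNAs were added, both conditions set beforehand were met. The one for it was met since the spike-in ratio fell with length (Spearman -0.6, permutation p = 0.00342, Pearson on log length -0.816, permutation p = 4e-05, and -0.763 without the 2 lengths farthest from the median), and the one against it since the slope per doubling of length was -1.05 (95% bootstrap interval -1.26 to -0.77) across spike-in RNAs and -0.69 (-0.81 to -0.56) across genes of that length, a difference of -0.37 (-0.61 to -0.05). Lengths of spike-in RNAs are exact, whereas those of genes are means over the models read. Error in the latter would flatten the slope across genes. The difference in slope therefore cannot decide whether the loss was equally strong for both, and does not argue against a technical loss as such. Spike-in RNAs do not come from the tissue, so their own trend with length is not a difference between the tissues. Whether a technical loss, of the same or another strength, made the trend across genes stays open, and no biological explanation was tested. A looser reading, that both slope intervals overlap, was tried after the result was seen and is not used. Truncation of molecules at the 5′ end in replicate 2 stays open, since the median per-gene difference in reads on models lacking that end alone was 0 percentage points over 1248 genes (468 higher in replicate 2 and 561 in replicate 1), but 0.00437 (95% bootstrap interval 0 to 0.246) with models lacking both ends added (626 and 473), both kinds together holding 8.47% of the reads of these genes in replicate 1 and 11.2% in replicate 2.

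The median log2 ratios of connective tissue and tendon genes were lower in replicate 2, with Mgp (0.27) and Scx (0.90) the members above 0. The length difference is argued against, since both lists stayed below all random lists matched on expression and length (percentile 0). For these libraries, a lower share of every non-muscle tissue is argued against as well, since the 18 connective tissue and tendon members had a median length-adjusted log2 ratio of -0.77 and the 21 endothelial, smooth muscle and macrophage members 0.05, a difference of -0.81 (permutation p = 0.00262). The permutation shuffled genes, which are not independent replicates, so its p does not measure the spread between samples. A different amount of tendon and fascia in the dissected pieces remains possible and was not tested, nor was a difference between the animals.

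Aldoa and Tnni2 gave the smallest p for a difference in model shares, with 73.8% and 92.8% of reads on other models. A candidate explanation is that the 2 files put 1 intron chain of each gene in different classes, since the lower adjusted p with chains joined was 0.414. In all, 676 of 20367 chains present in both libraries had another class in the other file. The test of both genes was no longer past its threshold with chains joined, and no biological explanation was tested.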

How the results depend on the processing

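The length adjustment, the restriction to complete models, the joined chains, the second definition of length and the chains without the most read one were chosen after seeing the data. Across all alternatives, 39 values of the main results stayed within their limits and 32 moved, and of the other results 132 stayed and 41 did not. Not counted are settings whose outcome is fixed, which are TMM for list percentiles, since it shifts every ratio alike, and leaving out 1 of 2 replicates for levels and shares, since either value lies within the SD of both. No gene list outside the central range of random lists turned to the other side with length matched. Of genes that differed, 548 were higher in replicate 1 and 522 in replicate 2, but the larger group was that higher in replicate 2 with TMM (663 against 266), the length adjustment (336 against 180), complete models (410 against 363) and no read minimum (469 against 431). The restriction to annotated genes for the agreement was not run, as it equals the main setting.

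With at least 5 reads, 8849 and 6796 annotated genes were detected. Transcript models numbered 29613 and 19840 with at least 2 reads and 13220 and 8774 with at least 5. The correlation between the libraries was 0.868 with a pseudocount of 0.5, 0.944 with 5 and 0.873 across annotated models. With the length adjustment, 516 genes differed. With annotated models only, fast fibre genes stood at 137700 CPM, the Myh4 share at 57.3% and the Atp2a1 share at 7.76%. Genes with different model shares numbered 395 with all models and 11 with annotated models. The median leading share was 84.5% with all models, 99.5% with annotated models, 93.3% and 96.4% with minimums of 20 and 100 reads, and 95.3% to 95.5% when either replicate was left out. The annotated class held 23.3% when each model counted once and 72.7% and 74.7% with at least 2 and 5 reads. Unannotated chains of replicate 1 found in replicate 2 made up 54.2% and 87.8% with at least 2 and 5 reads, and 21.8% as single junctions, and those of replicate 2 found in replicate 1 79.6%, 97.6% and 39.6%. The cause of these shifts was not tested, except that higher minimums leave fewer models. Depth limits genes under about 3 reads, and 61.0% and 60.3% of models rest on 1 read.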

Other observations

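Genes of blood and nerve were among those higher in replicate 2. Of 5 tested erythroid genes, 3 were higher in replicate 2, among them Hba-a1 with a log2 ratio of 0.96. When adjusted over the list alone 5 passed, 4 of them higher in replicate 2 and 1, Alas2 (log2 ratio -1.67, 19 and 3 reads), higher in replicate 1. Of the Schwann and nerve genes 3 were also higher in replicate 2, with Pmp22 at 0.54, and 3 passed when adjusted over the list alone. The erythroid list stood at percentile 97.1 of random lists matched on expression and 74.9 when transcript length was matched too, the Schwann and nerve list at 96.5 and 99.2. Mitochondrially encoded genes, with a median log2 ratio of -0.32, stood at percentile 21 and, with length matched, 0.09, whereas their summed level was higher in replicate 2 (1929 against 1455 CPM), with mt-Cytb at a log2 ratio of 1.75. Ribosomal protein genes had a median log2 ratio of 0.42 at percentile 97.3, and at 30.4 with length matched.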
